A study of Mus musculus with 6 samples.

How the data were processed

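RNA from the tibialis anterior of 6 male C57Bl/6 mice was hybridised to Affymetrix whole-transcript arrays, 3 from sham-operated and 3 from castrated mice. Per the labels' protocols, about 25 mg of muscle was homogenised, total RNA was extracted on columns with DNase treatment, and 300 ng was labelled with biotin. The deposited values are log2 expression values per probe set, which the authors normalized before deposit. Partek is named in the submitters' processing notes without a version. The background correction, summarization and normalization are not given in the sources used here. Arrays have no read depth, and the number of arrays limits the precision. A normalization that makes arrays alike can compress differences at the dim and bright ends, so the values were also normalized again in other ways.

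Samples were grouped by the sham or castrated of their titles. No batch or scan information was used here. The diet label follows the surgery in all 6 samples, so it could not enter the model as a covariate. The labels do not state that each sample is a different animal beyond naming a mouse for each, so p-values measure the spread between these samples.

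The table holds 41345 probe sets. Of these, 23521 carry 1 gene symbol in the platform annotation, 1814 carry several and 16010 carry none. Symbols were updated through Entrez identifiers against a mouse gene table of assembly GRCm38.p6, in which 23328 of the 1-symbol probe sets matched. No genome build is named in the sources used here, so no coordinates are given. Each gene was represented by the probe set with the highest mean over the 6 arrays, which gave 22180 genes, of which 1082 had more than 1 probe set. No filter on dim genes was applied. Probe sets with several or no symbols were not used as genes.

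Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, castrated minus sham, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 36 gene lists hold 685 genes, of which 627 were measured. They cover androgen-responsive genes, polyamine metabolism, the clock, fasting, refeeding, glucocorticoid targets, atrophy, proteasome, autophagy, mTORC1, IGF and myostatin, stress responses, energy metabolism, fibre types, junction genes, matrix, and markers of other cell types. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists tested. Members were also adjusted over their list alone, which does not account for the number of lists. Camera with an estimated correlation, camera on ranks and fry were alternatives.

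Genes were named by a fixed rule. The first part takes genes past the threshold with groups that do not overlap, up to 12 per direction, without unnamed gene models and receptor or small RNA genes. Where fewer pass, each direction is filled to 6 by smallest p, and the added genes are given as values that did not pass. The second part takes the 4 members with the smallest p of each list that passed and 2 of other lists. The last part is a set of genes given whatever their values. Of that set, 18 were measured. Amd1 and Per2 had no probe set naming 1 gene alone and were not analysed here, and a further gene of the set is not reported here.

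Alternatives were quantile normalization, centring on array medians, filters at the 25th and 50th percentile of mean level, the mean of all probe sets of a gene, every probe set on its own, the replicate number as a block, a trended robust variance prior, no variance moderation, array weights, other thresholds, and leaving out each sample. Cyclic loess normalization, and the trended robust prior together with the filter at the 50th percentile, were added after seeing the data. The procedure was tested on simulated data for castrated against sham, with 200 of 22180 genes changed. It recovered 10% of genes changed by 0.5 on the log2 scale, 72% at 1, 94% at 1.5 and 96% at 2, with 7 false calls. With no gene changed it made 0 gene calls and 0 list calls. The simulated genes varied independently, whereas the estimated correlation was 0.33 for oxidative phosphorylation genes and 0.77 for tendon markers. The 0 list calls therefore do not show how often the preset correlation calls lists whose members vary together. A simulated list of 39 independent genes shifted by 0.12 had an adjusted p of 4.47e-11 with the preset correlation and an adjusted p of 0.154 with an estimated correlation. Figures were drawn with matplotlib 3.10.9.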

Results

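Gene expression was measured in the tibialis anterior, a fast-twitch muscle at the front of the lower leg, of male mice 7 weeks after surgery. Mice were sham-operated or castrated at 11 weeks of age and sampled at 18 weeks, with 3 samples in each group. Castration removes the testes, the main source of circulating androgen, and the series asks how muscle gene expression changes after it. The samples also differ in a feeding label, which reads fasted for the 3 sham and refed for the 3 castrated samples. The series design describes mice that stayed fasted and mice given food for 30 minutes, all then without food for 4 hours, whereas the protocol attached to every sample describes the meal for all mice. Surgery and feeding label split the samples identically, so every difference reported here is between castrated mice labelled refed and sham mice labelled fasted. Median log2 values were between 5.04 and 5.10 on the 6 arrays. Arrays correlated across the 22180 genes at 0.9904 to 0.9924 within a group and at 0.9895 to 0.9916 between groups. The first principal component held 24.7% of the variance, and the others held 21.3%, 20.3%, 17.9% and 15.7%, so none dominated. All sham samples lay on the negative and all castrated samples on the positive side of the first. Furthest out were sham sample 3 (−0.69) and castrated sample 1 (0.55).

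Castrated muscle had more Actc1, the cardiac alpha-actin that is also expressed in developing skeletal muscle, and less C7, a component of the terminal complement complex, and Slc15a5, a member of the peptide transporter family. Actc1 (Entrez 11464) rose from a log2 value of 9.16 ± 0.057 to 10.76 ± 0.093 (SD, n = 3 each), a 3.04-fold increase (standard error 0.098 on the log2 scale, limma adjusted p = 0.00136). C7 (Entrez 109828) went from 7.62 ± 0.10 to 5.54 ± 0.28 and was 4.23-fold lower (log2 difference −2.08, standard error 0.15, limma adjusted p = 0.00221). Slc15a5 (Entrez 277898) went from 5.95 ± 0.18 to 4.19 ± 0.16 and was 3.37-fold lower (log2 difference −1.75, standard error 0.13, limma adjusted p = 0.00221). Its castrated mean lay under the array medians of 5.04 to 5.10, and whether it was above background was not tested. These were the 3 genes of 22180 past the threshold, 1 higher and 2 lower, and each had all castrated samples on 1 side of all sham samples. At an unadjusted p under 0.05 there were 1581 genes, 802 higher and 779 lower, where 1109 are expected with no difference. The groups did not overlap for 2828 genes, or 12.8%, against 10% by chance. Without variance moderation 0 genes passed, and the adjusted p of Actc1 was then 0.312, while that of C7 and Slc15a5 was 0.669. With every probe set tested on its own only Actc1 passed. With the replicate number as a block Slc15a5 did not pass (limma adjusted p = 0.0599).

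The next genes by p had values that did not pass the threshold over all genes. Higher in castrated samples were the glutathione transferase Gstm2 (log2 difference 1.10, standard error 0.15), the stress-inducible Gadd45g (0.88, standard error 0.12), the complement gene C1s2 (0.83, standard error 0.11), the corneal and tendon proteoglycan keratocan, Kera (0.89, standard error 0.15), and the sodium pump subunit Atp1b2 (0.78, standard error 0.14). C1s2 lay at the 4.5th percentile of mean level, where arrays measure little. Lower were Sbk2, a putative kinase (−1.06, standard error 0.13), Odc1 (−0.80, standard error 0.11), the muscle zinc-finger gene Mss51 (−1.91, standard error 0.27) and Samd10 (−0.80, standard error 0.11). Their limma adjusted p ran from 0.128 for Sbk2 and C1s2 to 0.376 for Atp1b2. Sbk2, Gadd45g, Gstm2, Mss51, Odc1 and Samd10 did pass when genes under the 25th percentile of mean level were left out, with adjusted p between 0.0218 and 0.0371.

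**Figure D1:**
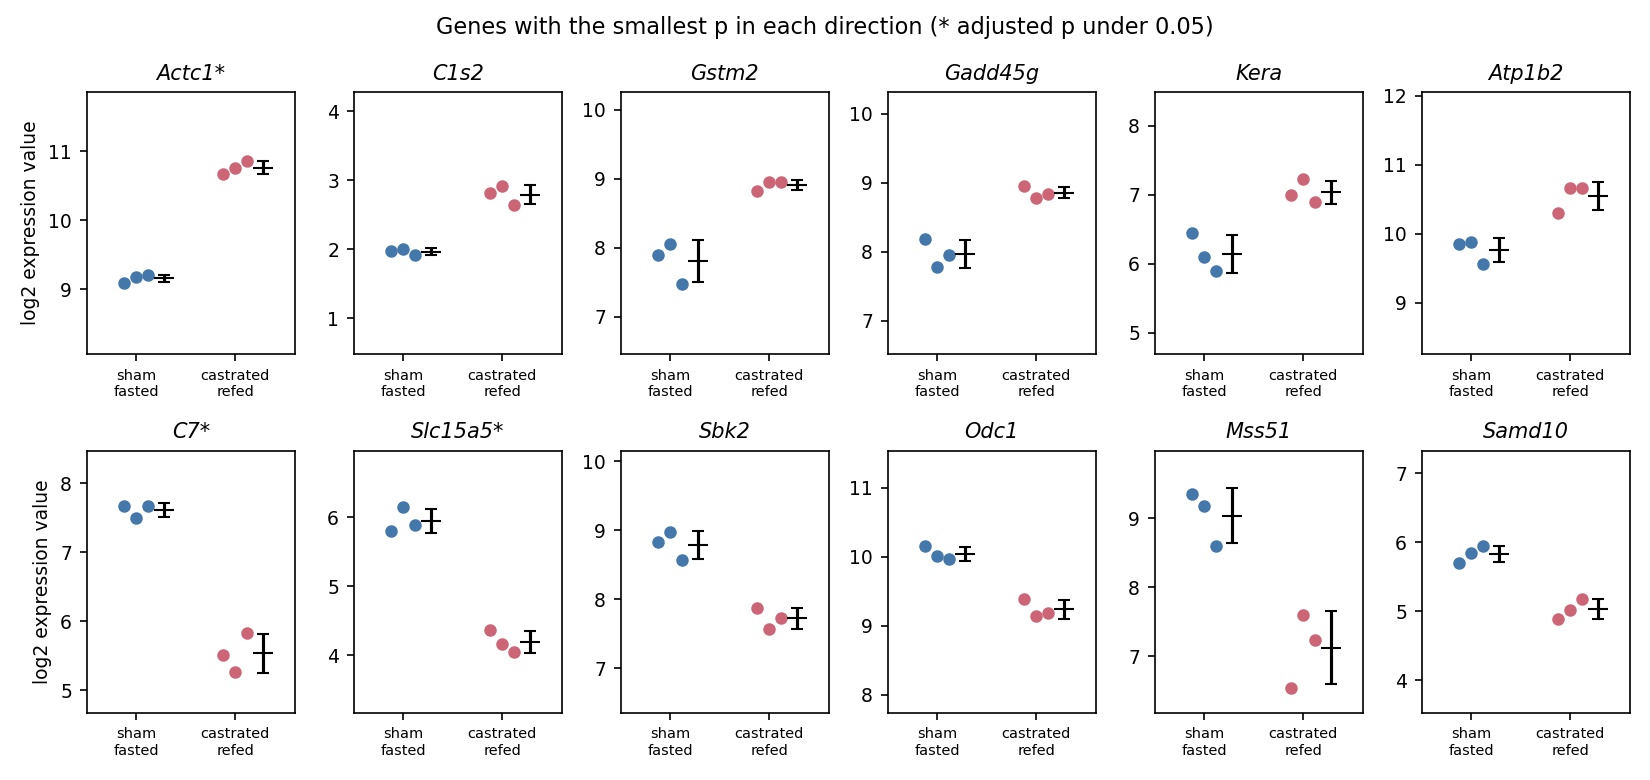
Log2 expression values of the 12 genes with the smallest p by direction, higher in castrated samples in the upper row and lower in the bottom row. Each point is a sample, the horizontal mark and bar are the mean and SD of 3 samples, each panel has its own axis of equal span, and an asterisk marks the 3 genes with an adjusted p under the threshold.

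Genes of polyamine metabolism were lower in castrated muscle, led by enzymes that make and oxidise polyamines. Odc1, ornithine decarboxylase, makes putrescine and was 1.74-fold lower, and Smox, spermine oxidase, was 1.83-fold lower (log2 difference −0.87, standard error 0.23). Azin1, which protects ornithine decarboxylase from degradation, differed by −0.35 and spermidine synthase, Srm, by −0.24. Of 10 measured members 6 were lower, with a median log2 difference of −0.15, and the list passed the set test (camera adjusted p = 0.0214). It did not pass with an estimated correlation (adjusted p = 0.669), on ranks (adjusted p = 0.219), after quantile normalization (adjusted p = 0.0865), or without sham sample 1 (adjusted p = 0.178). No member passed over all genes, and adjusted over the list alone Odc1 and Smox did. The androgen-responsive list, which also holds Odc1 and Smox, had 4 of 8 members higher and 4 lower and did not pass (camera adjusted p = 0.505), and adjusted over the list alone the same 2 genes passed. Camera tests a shift of a list in 1 direction, so this does not show that its genes were unchanged. For changes in either direction fry gave this list an unadjusted p of 6.61e-05. Other values from that list were 0.21 for Igf1, a muscle growth factor, 0.39 for Mstn, the growth inhibitor myostatin, and −0.32 for Fkbp5, a steroid-receptor chaperone. With a sample left out, Igf1 ran from 0.099 without castrated sample 3 to 0.31 without castrated sample 2, Mstn from 0.12 to 0.53 and Fkbp5 from −0.55 to −0.11, so none of these sizes is firm.

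Clock genes differed in opposite directions. Arntl, the activating clock factor BMAL1, was 1.57-fold lower (log2 difference −0.65, standard error 0.12), while the repressors Per3 (0.64, standard error 0.15) and Per1 (0.37, standard error 0.091) were higher. Adjusted over the list alone these 3 of 17 measured clock genes passed, and none passed over all genes. Per1 is named here as 1 of the 2 glucocorticoid targets with the smallest p. The clock output gene Dbp differed by 0.38 and the repressor Nr1d1 by −0.23, and without castrated sample 2 these were 0.22 and −0.093. The list as a whole did not pass (camera adjusted p = 0.794), and its median was −0.056 while the test's direction was higher. For changes in either direction fry gave the clock list an unadjusted p of 0.00402.

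Lists tied to feeding, hormones and muscle wasting did not pass. Fasting-induced genes had a median of −0.033 (camera adjusted p = 0.463) and refeeding- and insulin-induced genes a median of −0.080 (camera adjusted p = 0.237). The ubiquitin ligases of atrophy Fbxo32 and Trim63 differed by −0.35 and −0.41, and their list by a median of −0.13 (camera adjusted p = 0.119). The Fbxo32 value was −0.57 without castrated sample 3 and −0.23 without castrated sample 1, and the Trim63 value ran from −0.25 without castrated sample 2 to −0.64 without castrated sample 3. Ddit4, an inhibitor of mTORC1, differed by 0.58, Pdk4, which limits glucose oxidation, by −0.10, Foxo1 by −0.029, hexokinase Hk2 by −0.080 and the lipogenic factor Srebf1 by −0.21. With a sample left out, Pdk4 ran from −0.16 to −0.031, Hk2 from −0.15 to −0.032 and Srebf1 from −0.27 to −0.11. Foxo1 changed sign under quantile normalization (0.0070). Glucocorticoid targets had a median of −0.029 against a test direction of higher (camera adjusted p = 0.794), and Sgk1 and Per1 passed adjusted over the list alone, with Sgk1 at 0.63. Neither gene passed over all genes (limma adjusted p = 0.473 for Sgk1 and 0.486 for Per1). The mTORC1 regulators (median −0.011, camera adjusted p = 0.712) and the autophagy and lysosome list (median −0.069, camera adjusted p = 0.105) did not pass. IGF and myostatin signalling (camera adjusted p = 0.658) had a median of −0.042 against a test direction of higher. Id1, a target of BMP signalling, passed adjusted over the list alone at 0.62 but not over all genes (limma adjusted p = 0.391).

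**Figure D2:**
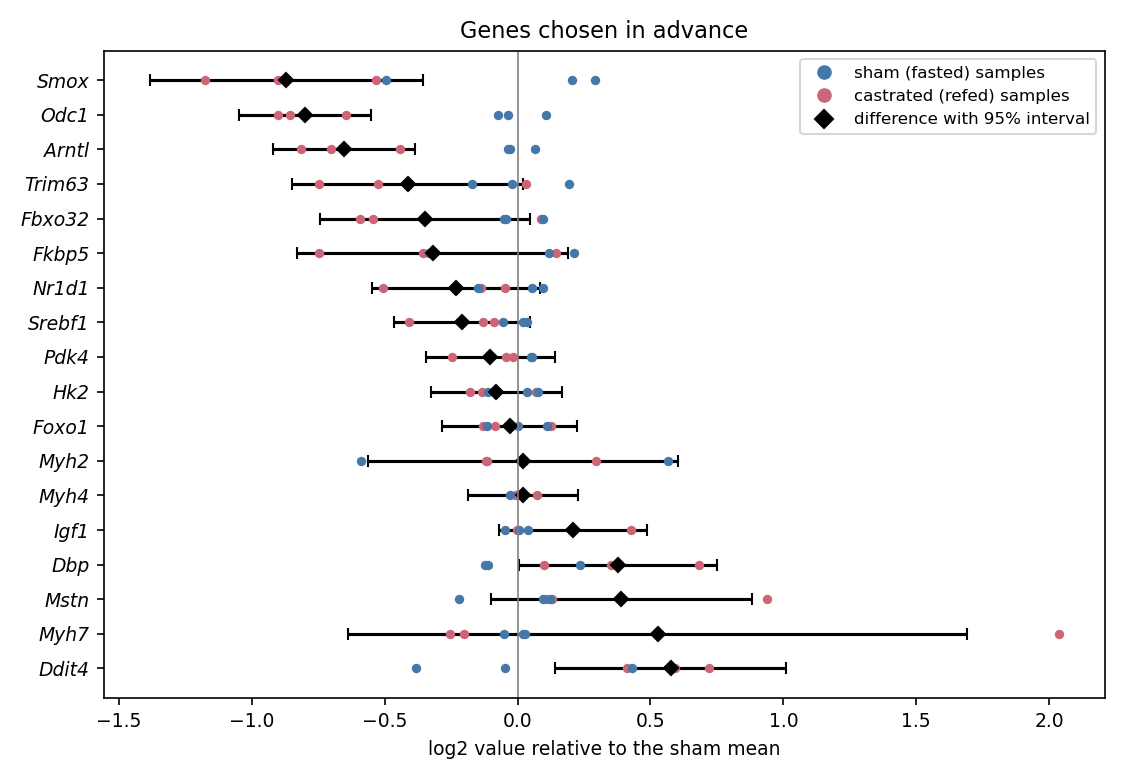
Genes that were to be reported whatever their values, as log2 values relative to the sham mean. Blue and red points are the 3 sham and 3 castrated samples, the black diamond is the difference with its 95% interval, and the intervals of Odc1, Smox and Arntl lie below 0, those of Ddit4 and Dbp lie above 0, and Myh7 rests on castrated sample 1.

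Oxidative phosphorylation, proteasome, ribosome biogenesis, NRF2 target and stress response genes were lower by small amounts across many members. Of 39 oxidative phosphorylation genes 34 were lower, with a median of −0.12, a change of −7.67% on the linear scale (camera adjusted p = 3.60e-05, adjusted p = 0.669 with an estimated correlation). Ndufs4 of complex I differed by −0.38 (standard error 0.097), and the cytochrome oxidase subunits Cox4i1, Cox5b and Cox7a1 by −0.42, −0.33 and −0.32. A second, dim probe set of Cox5b differed by 0.052. Of 30 proteasome subunits 29 were lower, with a median of −0.11 (camera adjusted p = 0.000156, adjusted p = 0.669 with an estimated correlation), among them Psmb5 (−0.29), Psmc5 (−0.28), Psmc4 (−0.23) and Psma5 (−0.37, with another probe set at 0.11). Of 24 ribosome biogenesis genes 19 were lower, with a median of −0.11 (camera adjusted p = 0.00533, adjusted p = 0.669 with an estimated correlation), among them Rrp9 (−0.24), Nop2 (−0.21), Gnl3 (−0.28) and Rrp12 (−0.22). Targets of the oxidative stress factor NRF2 were lower for 14 of 18 genes, with a median of −0.10 (camera adjusted p = 0.0258, adjusted p = 0.669 with an estimated correlation). Their members Gclm, Gpx1 and Gpx3 differed by −0.46, −0.30 and −0.28 and Gstm1 by 0.25. The integrated stress and amino acid response was lower for 17 of 24 genes, with a median of −0.12 (camera adjusted p = 0.0258, adjusted p = 0.669 with an estimated correlation). Adjusted over the list alone 3 of its genes passed, Ppp1r15a (−0.58), Mthfd2 (−0.40) and Vldlr (−0.44), all lower, while Chac1 differed by 0.48. In the other 4 lists no gene passed adjusted over the list alone, and in none of the 5 did a gene pass over all genes. The oxidative phosphorylation median was −0.072 without castrated sample 3, and the proteasome median −0.067 without sham sample 1 and −0.069 without castrated sample 1, with both lists still past the threshold. Per array, with each gene centred over the arrays, the proteasome median was 0.020 in castrated sample 3, above 0.0054 in sham sample 2, so the groups overlap. Among the named members, a left-out sample moved Gnl3 to −0.14 and Chac1 to 0.31 (without sham sample 3), Rrp12 to −0.14 (without sham sample 1) and Gpx3 to −0.18 (without castrated sample 1). After quantile normalization the ribosome biogenesis (adjusted p = 0.0997), NRF2 (adjusted p = 0.193) and stress response (adjusted p = 0.0596) lists did not pass. Ribosome biogenesis also did not pass without castrated sample 1 (adjusted p = 0.0759), NRF2 without sham sample 2 (0.193) or castrated sample 1 (0.129), and the stress response without sham sample 3 (0.237, median −0.057), castrated sample 1 (0.0556) or castrated sample 2 (0.0701).

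The tendon, adipocyte and extracellular matrix lists passed as higher in castrated samples, though other splits of the 6 samples gave larger absolute medians for each of them. Of 11 tendon markers 9 were higher, with a median of 0.48, or 1.39-fold (camera adjusted p = 8.10e-05, adjusted p = 0.669 with an estimated correlation), among them Kera (0.89), the tendon transcription factor Mkx (0.52), Comp (0.48) and Fmod (0.53). Of 13 adipocyte markers 11 were higher, with a median of 0.18 (camera adjusted p = 0.00608, adjusted p = 0.669 with an estimated correlation). Pparg, the main fat cell transcription factor, differed by 0.40, Fabp4 by 0.28, Car3 by 0.22 and Cidea by −0.36. Car3 and Fabp4 lay at the 99.9th and 99th percentile of mean level, while Adipoq and Plin1 lay at 47.8 and 45.2. Whether the Car3 and Fabp4 signal in this muscle came from fat cells was not tested. Of 27 extracellular matrix genes 21 were higher, with a median of 0.14 (camera adjusted p = 0.0117, adjusted p = 0.777 with an estimated correlation). Col14a1 differed by 0.49, Col1a1 by 0.87, Loxl1 by −0.34 and Timp1 by −0.33. Adjusted over the list alone 2 tendon markers, Kera and Mkx, 1 matrix gene, Col14a1, and 0 adipocyte markers passed, and none passed over all genes. Without sham sample 3 the tendon median was 0.29, Fmod 0.34 and Cidea −0.24, and without castrated sample 1 Comp was 0.31. The matrix list did not pass without sham sample 2 (adjusted p = 0.0946), sham sample 3 (0.542), castrated sample 1 (0.287) or castrated sample 2 (0.0560), and the adipocyte list without sham sample 2 (0.0501). The matrix median was 0.047 without sham sample 3, 0.054 without castrated sample 1, 0.23 without sham sample 1 and 0.22 without castrated sample 3. Per array the tendon markers' median, with each gene centred over the arrays, ran from −0.52 to 0.11 in sham and from −0.10 to 0.45 in castrated samples. These values overlap, as do those of the matrix list (−0.28 to 0.16 in sham and −0.10 to 0.19 in castrated samples).

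**Figure D3:**
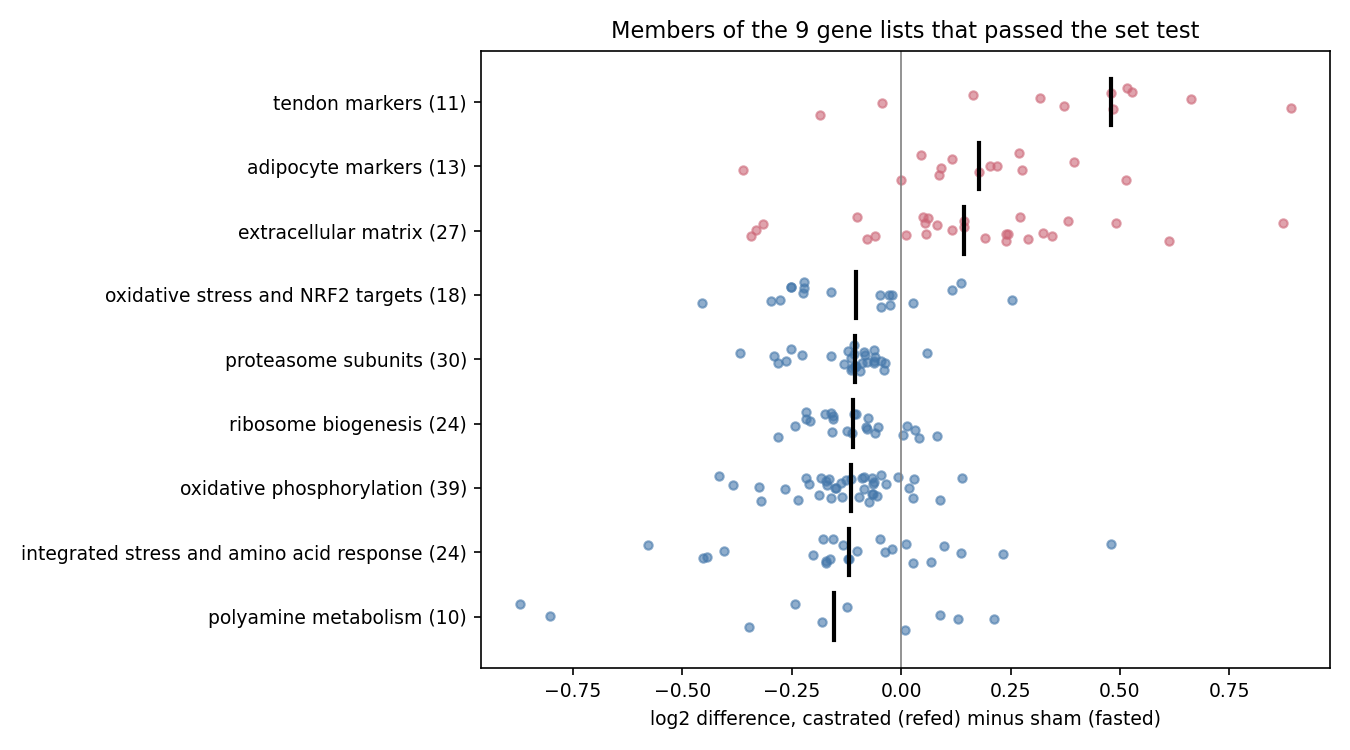
Log2 difference, castrated minus sham, of each measured member of the 9 lists that passed camera with the preset correlation, with the number of members in brackets. Each point is a gene, the black line is the list's median, and the medians run from −0.15 for polyamine metabolism to 0.48 for tendon markers.

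All 9 list calls, 3 higher and 6 lower, used the preset correlation. With camera at an estimated correlation, or with fry for a shift in 1 direction, 0 lists passed. The smallest adjusted p were 0.669 and 0.287, and at an unadjusted p under 0.05 the counts were 0 and 4. Fry's p for changes in either direction is not part of these counts. Other splits of the same 6 samples into 3 and 3 gave between 1 and 8 lists by the preset test, against 9 for the real groups, and 0 genes, against 3. The largest absolute median in another split was 0.30 for the matrix list, against 0.14 for the real groups, 0.54 against 0.48 for tendon, 0.19 against 0.18 for adipocytes and 0.117 against 0.105 for the proteasome, and lower than the real one for the other 5 lists. The matrix list was called in 6 other splits, tendon in 3, proteasome and oxidative phosphorylation in 2, adipocyte, ribosome biogenesis and NRF2 in 1, and polyamine and stress response in 0.

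The fibre-type lists did not pass. The fast fibre list had a median of 0.016 (camera adjusted p = 0.858), with the fast myosin Myh4 at 0.021 and Myh2 at 0.020 (standard error 0.26). With a sample left out Myh2 ran from −0.27 to 0.30, so its direction is undetermined. Slow fibre genes had a median of 0.25 (camera adjusted p = 0.194), which rests on castrated sample 1. With each gene centred over the arrays, their median was 0.54 in that sample, −0.23 and −0.17 in the other castrated samples and between −0.26 and −0.041 in sham. The slow myosin Myh7 differed by 0.53, but it stood at 7.41 in castrated sample 1 and between 5.11 and 5.40 in the others, and without that sample it differed by −0.23. Denervation and junction genes had a median of −0.037 (camera adjusted p = 0.578). Musk, the junction's receptor kinase, was at −0.81 and passed adjusted over the list alone but not over all genes (limma adjusted p = 0.391). Fatty acid oxidation had a median of −0.042 (camera adjusted p = 0.578). Its regulator Ppargc1a, at 1.09 (standard error 0.24), passed adjusted over the list alone but not over all genes (limma adjusted p = 0.446). Glycolysis and glycogen genes (median −0.043, camera adjusted p = 0.251), cholesterol synthesis (−0.040, adjusted p = 0.301), heat shock (0.018, adjusted p = 0.566), cell cycle (−0.046, adjusted p = 0.230) and interferon response (0.021, adjusted p = 0.194) did not pass. Immediate early genes (median −0.11, camera adjusted p = 0.230) held 3 genes that passed adjusted over the list alone, Fos (−1.18), Maff (−0.41) and Nr4a3 (1.34), of which Nr4a3 was chosen after its values were seen. None of the 3 passed over all genes (limma adjusted p = 0.486, 0.489 and 0.544).

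Markers of other cell types did not pass. Fibro-adipogenic markers had a median of −0.13 (camera adjusted p = 0.181), macrophage markers −0.074 (0.237), lymphocyte and neutrophil markers −0.018 (0.790), endothelial markers 0.017 (0.713), pericyte and smooth muscle markers 0.017 (0.858) and Schwann cell and nerve markers 0.091 (0.435). The endothelial junction gene Cldn5 differed by −0.65 and passed adjusted over the list alone but not over all genes (limma adjusted p = 0.486). Satellite cell and regeneration genes had a median of 0.020 against a test direction of lower (camera adjusted p = 0.911). For changes in either direction fry gave this list an unadjusted p of 9.11e-06. Only 2 of the erythrocyte markers were measured and their list was not tested; they differed by 0.076 for Epb42 and −0.022 for Slc4a1.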

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

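Cyclic loess normalization and the trended prior on bright genes were chosen after seeing the data. The 3 genes that passed were called again under quantile normalization, median centring, cyclic loess, array weights, probe set means and in each fit that left out a sample, which gave 3 to 4 genes. Counts changed to 9 without genes under the 25th percentile of mean level, 16 without those under the 50th, 10 with a trended robust prior, 28 with that prior on genes above the 50th percentile, 1 (Actc1) for every probe set on its own, and 0 without variance moderation. Slc15a5 lies under the 50th percentile and was not tested there. Unadjusted p under 0.05 gave 1581 genes, and 126 with a 1.5-fold change. Filters and single probe sets change the number of tests and also the features from which the variance prior is estimated. On the same values, the unadjusted limma p of Actc1 was 6.15e-08 over genes and 1.04e-06 over every probe set. The number of tests alone therefore does not account for the count over single probe sets. How much each contributed, and the cause of the other changes, was not tested.

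List counts were 5 under quantile normalization and 5 under cyclic loess, which both lost polyamine metabolism, the stress response, ribosome biogenesis and NRF2 targets, 0 with an estimated correlation and 0 with fry. They ran from 7 to 13 when a sample was left out, and from 6 to 10 under the other settings. Array weights lost the stress response (adjusted p = 0.0646) and matrix (0.124), the filter at the 50th percentile and camera on ranks each lost polyamine metabolism, the stress response and NRF2 targets. The cause was not tested.

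Signs changed for Foxo1 (0.0070 under quantile normalization, 0.0097 under cyclic loess, 0.0059 with array weights), Myh4 (−0.017) and Myh2 (−0.017) under median centring, which shifts every gene alike. With a sample left out, Foxo1 ran from −0.11 to 0.026, Myh2 from −0.27 to 0.30, Myh4 from −0.0061 to 0.035 and Myh7 from −0.23 to 0.92. None passed the threshold and the cause was not tested.

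Same-numbered samples of both groups had correlated deviations of 0.076, 0.033 and 0.047, so the numbers were not taken to pair samples, although every sample correlated best with its own number. With the replicate block 2 genes passed, Slc15a5 having an adjusted p of 0.0599, and 9 lists. Dim genes such as C1s2 are limited by signal over background.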

Other observations

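The families, and the tests on single lists, were chosen after the results were seen; the feeding and split tests were written before. Among 259 gene families formed from symbol stems, 9 passed camera with the preset correlation and 0 with an estimated one (adjusted p = 0.906 for each). Large-subunit mitochondrial ribosomal protein genes (Mrpl) were lower for 39 of 43 members (median −0.12, camera adjusted p = 0.000124), and none of them is in a fixed list, while the small-subunit genes (Mrps), lower for 19 of 28, did not pass (median −0.067, camera adjusted p = 0.156). Small nucleolar RNA genes of the Snord family were lower for 42 of 47 members (median −0.18, camera adjusted p = 0.000220), and host genes (Snhg) for 14 of 15 (median −0.15, camera adjusted p = 0.0313), while those of the Snora family, lower for 18 of 26, did not pass (median −0.13, camera adjusted p = 0.282). Protocadherin beta genes, which lie among the dim probe sets, were higher for 18 of 22 members (median 0.13, camera adjusted p = 0.0457).

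The 17824 probe sets not used as genes gave 0 calls in limma at an adjusted p under 0.05 (smallest adjusted p = 0.654) and 1431 at an unadjusted p under 0.05, where 891.2 are expected. On sham sample 1, 24 probe sets lay over 3 log2 units under every other array, against 2 on sham sample 2, and none of them is a tested gene.

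Feeding and surgery cannot be told apart, because the labels split the samples identically. If refeeding had set the differences, fasting-induced genes should be lower and refeeding-induced genes higher in castrated samples. The fasting list had a median of −0.033 (limma camera, unadjusted, 0.291) and the refeeding list −0.080 (0.122), which decides neither way. The real split gave 3 genes against at most 0 in the others and 9 lists against at most 8. Of the 10 splits 1, the real one, gave as many genes, and 1 as many lists, but 10 splits are too few for a share under 0.05.

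Oxidative phosphorylation, proteasome and ribosome biogenesis genes were lower together. An intensity trend or a single array was first tested over all 3 lists at once, which left both open, and then by part: after cyclic loess normalization the oxidative phosphorylation and proteasome medians shrank from −0.12 to −0.081 and from −0.11 to −0.069, with adjusted p of 0.00253 and 0.0145, and without any array their pooled genes kept a median of −0.090 or lower and each list −0.067 or lower, with adjusted p of at most 0.0278. The parts were formed after the result over all 3 lists was known, and the adjusted p use the preset correlation. Neither cyclic loess nor leaving out any array took the 2 medians to 0. Random lists matched on mean level had typical medians of −0.025 for oxidative phosphorylation and −0.035 for the proteasome, against −0.0056 over all genes. These values and the shrinkage go with an intensity-dependent part of the 2 shifts, whose source was not tested. A single array as part of the cause stays open for these lists. For ribosome biogenesis, with matched random lists at −0.041, an intensity trend and a single array both stay open. After cyclic loess its median went from −0.11 to −0.083 (camera adjusted p = 0.0855). With a sample left out its median closest to 0 was −0.088, and it was not past the threshold without castrated sample 1. Of 10000 random lists matched on mean level, 0 had a median as low as oxidative phosphorylation, 36 as the proteasome and 104 as ribosome biogenesis. The random lists hold unrelated genes, whereas the estimated correlation within these lists was 0.33, 0.26 and 0.050. Medians of members that vary together spread more, and the 3 lists were picked because they passed, so these counts are not p-values. Variation between individual mice that list members share may account for the oxidative phosphorylation and proteasome shifts. For the proteasome another split gave an absolute median of 0.117 against 0.105, which met the prediction. For oxidative phosphorylation no other split reached the real median (at most 0.112 against 0.115), though 2 other splits also called the list. For ribosome biogenesis the other splits reached at most 0.082 against 0.109 and 1 called the list, which leaves it open there too. A lower share of myofibre RNA also stays open. The 14 fast fibre and glycolytic genes with a mean log2 value between 8 and 12 had a median of −0.043 (bootstrap over genes −0.11 to 0.035). That range was chosen after results were seen and leaves out brighter genes such as Myh4, and the whole fast fibre list had a median of 0.016. The bootstrap resamples genes that vary together, so it does not measure the spread between mice. Castration or feeding remain untested.

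Tendon markers were higher, and tendon carried over at dissection may be a source. A first test over 10 abundant tendon transcripts, 9 of them higher with a median of 0.43, met its prediction, but 4 of the 10 belong to the tendon list itself, so it was replaced after its result was known. Over the 6 outside the list, 5 were higher, with a median of 0.19 (bootstrap over genes 0.050 to 0.74), Col1a1 at 0.87 and Dcn at −0.015, which neither excludes nor meets the prediction that all 6 rise. These 6 were part of the first test, so their values were already known. The 5 higher ones, Col1a1, Col1a2, Bgn, Lum and Sparc, also belong to the matrix list. The bootstrap resamples genes that vary together, so it does not measure the spread between mice. Variation between mice also may account for it, as another split gave a median of 0.54 against 0.48 for the real groups. Muscle fibroblasts express many of these genes too, and a change in them with castration stays open as untested.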
